A study of Sorghum bicolor with 8 samples.

How the data were processed

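Gene expression was measured by RNA sequencing in prop roots, the aerial roots that grow from the lower stem, of Sorghum bicolor cultivar BRS330. Per the labels' protocols, plants grew in soil with 1.5 L of water per day until 60 days after planting and then received 0.45 L per day, a cut of 70%, for 30 days. The labels put 4 libraries in the ambient CO2 group (400 µmol per mol) and 4 in the elevated CO2 group (800 µmol per mol), and all 8 came from plants under water deficit. Per the labels' protocols, total RNA from 100 mg of ground tissue went into libraries made with the Illumina TruSeq Stranded mRNA kit. Nothing in the labels says whether the 4 libraries of a group came from separate plants.

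The submitters' processing notes name Trimmomatic 0.36, HISAT2, Cufflinks 2.2.1 and Cuffdiff, with no settings. Gene identifiers carry the annotation suffix 3.2, per the file headers and cells; the genome build is not given in the sources used here. The authors deposited 1 table of 34129 genes and 4 subsets of it, in the column layout that Cuffdiff writes. Each gene has 1 FPKM value per group (fragments per kilobase of transcript, scaled to library size), pooled over the group's libraries by the authors. The deposited table also holds the log2 ratio of elevated over ambient FPKM, a test statistic (a score with no fixed range), a p-value and a q-value for each gene, all computed by the authors. No column holds the value of a single library, so no spread between replicates, no SD and no test of a different design could be computed. Read depth is unknown, and no interval or detection limit based on counts is given for a gene's level. A p-value from this table rests on the authors' model of the spread between libraries, which cannot be checked here. How the authors' library normalization was set is not given in the sources used here.

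The deposited log2 ratios were checked against the FPKM values and differed by at most 1.27e-05. The deposited q-values were checked against a Benjamini-Hochberg adjustment over the 16280 tested genes and differed by at most 5.25e-07. The smallest deposited p-value is 5e-05, shared by 726 genes, so genes beyond that point cannot be ranked by p. In 1 of the subsets the authors replaced a value of 0 by 1e-05 in 3 genes, which turns an undefined ratio into log2 values as large as 19.5 and as low as -19.1; those replaced ratios were not used. This subset and another held the 1865 significant genes of the full table, and the other subsets held the 394 with a positive and the 1471 with a negative log2 ratio.

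A gene was called changed when the authors' test had been run and the deposited q-value was under 0.05. This threshold, the comparison and most alternatives were fixed before the data were examined. The rule for named genes was also fixed then: where no gene names are at hand, the 2 called genes with the largest rise and the 2 with the largest fall, with at least 1 FPKM in the higher group and a value above 0 in both. A further part of the plan was to test 40 lists of genes defined by product names, among them photosynthesis, cell wall, drought response, hormone and cell type lists. It was not run: the files pair the identifiers with no names, and 0 of them matched the 32945 genes of the RefSeq table at hand (assembly Sorghum_bicolor_NCBIv3), which carries no product names. No list therefore has a result, and genes are described by position, level and locus span.

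Calls on each chromosome were compared with calls on all others by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 20 tests. Neighbouring genes were taken as consecutive genes in the order of their deposited loci, both tested. The number of neighbouring pairs called in the same direction was compared with 9999 shuffles of the calls within chromosomes, by a one-sided permutation test whose smallest possible p is 0.0001. A run was a set of called genes of the same direction with at most 1 other annotated gene between consecutive members; runs were compared with 999 shuffles. Called shares of short and long loci were compared by shuffling calls within expression deciles. Loci are printed as deposited, and whether starts count from 0 or 1 is not given in the sources used here. Locus span is the deposited end minus start; where genes overlap the table gives them a common locus, which is the case for 4052 genes. Genes are not independent replicates, and these tests describe where the calls of this table fall, not the spread between plants. The tests on neighbours, runs, span, common loci and gene density were chosen after the data had been seen. Shares carry 95% Wilson intervals, which cover counting error over genes only.

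The neighbour and span tests were tried on simulated calls over the 16280 tested genes. With 60 planted neighbouring pairs the neighbour test passed in 20 of 20 simulations, and without them in 0. Calls without planted pairs came from the same shuffling as the test, so they cannot show how it behaves when neighbours depend on each other. The span test passed in 20 of 20 simulations with a planted difference and in 2 of 20 without. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered the q threshold, a minimum fold change, minimum levels of 1 and 5 FPKM, pseudocounts of 1 and 0.1, centring, a recomputed q-value and, added later, genes with common loci, genes with intermediate identifier numbers and runs.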

Results

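Transcript levels were compared in sorghum prop roots that had been under water deficit for 30 days, in air of 800 µmol per mol CO2 (elevated, 4 libraries) or 400 µmol per mol (ambient, 4 libraries). The table lists 34129 genes on 10 chromosomes and unplaced scaffolds, each with 1 pooled FPKM value per group. Expression of at least 1 FPKM was reached by 18228 genes in the ambient group and 17830 in the elevated group. FPKM summed over all genes came to 652743 in the ambient group and 579715 in the elevated group. In the ambient group the 50 highest genes held 12.9% of the summed FPKM, and in the elevated group 12.8%. The authors tested 16280 genes (47.7%), none of them below 2.03 FPKM in its higher group. Values of single libraries were not analysed here, so group values are printed without an SD, and every call rests on the q-value of the authors' deposited table.

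The comparison asks how elevated CO2 alters gene expression in prop roots of plants short of water. Under elevated CO2, 1471 genes fell and 394 rose in the authors' deposited table, out of 16280 tested. Genes that fell made up 78.9% of the 1865 called (95% Wilson interval 77.0 to 80.7%). Falls were also larger: the median fall was 2.55-fold (log2 -1.35, quartiles -1.81 and -1.05), and the median rise was 2.09-fold (log2 1.07, quartiles 0.88 and 1.35). A change of at least 1 on the log2 scale was shown by 78.7% of the genes that fell with a defined ratio (1157 of 1470) and by 57.4% of those that rose (225 of 392). Changes of at least 2 on that scale numbered 254 among falls and 20 among rises.

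The tested genes as a whole leaned less to falls than the called genes did. Over all tested genes the median log2 fold change was -0.03, with 8689 genes lower and 7591 higher. Among the 10633 genes with an unadjusted p above 0.2 in the authors' deposited table, 48.2% were lower under elevated CO2. Between p of 0.05 and 0.2 the share was 50.3%.

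**Figure D1:**
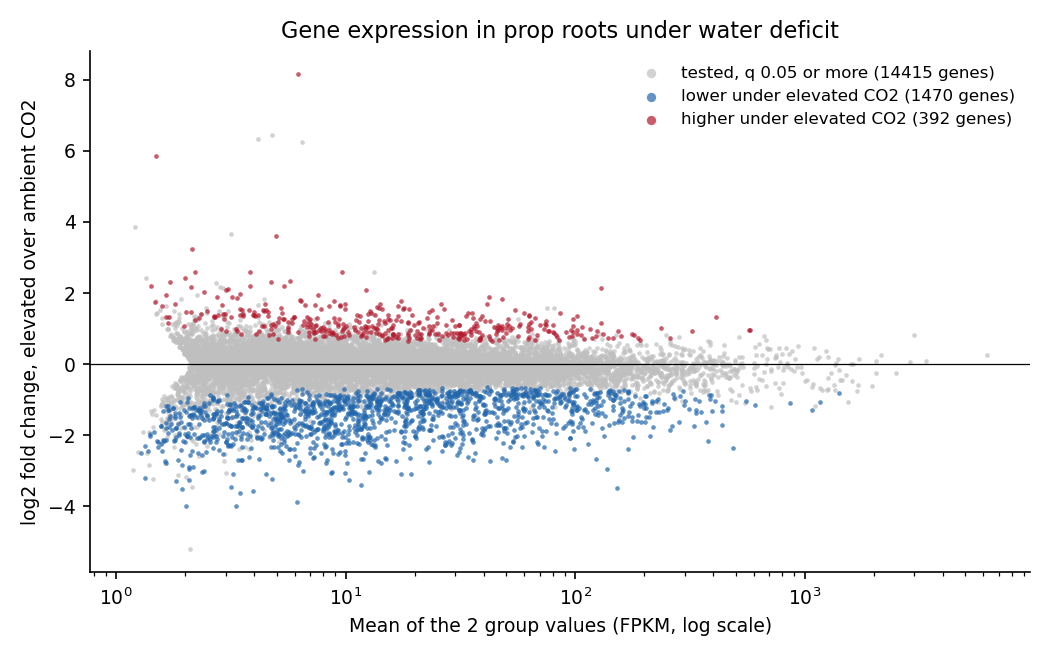
Each point is a tested gene, with the mean of its 2 group values in FPKM on a log axis and the deposited log2 fold change of elevated over ambient CO2; called genes that fell are blue, called genes that rose are red, and 3 called genes listed at 0 in a group are not drawn. The 1470 blue points outnumber the 392 red points at low and at high expression, and the smallest called changes lie near 0.64 (falls) and 0.65 (rises) in absolute log2 units.

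Falls outnumbered rises at each expression level examined. Of the 3078 tested genes below 5 FPKM in their higher group, 197 fell (6.40%) and 40 rose (1.30%). Between 5 and 20 FPKM, 536 of 6750 genes fell (7.94%) and 155 rose (2.30%). From 20 to 100 FPKM, 515 of 5132 genes fell (10.04%) and 154 rose (3.001%). At 100 FPKM and above, 223 of 1320 genes fell (16.9%) and 45 rose (3.41%), and the median log2 fold change of all genes tested in that class was -0.20. Genes that fell and genes that rose had similar levels, with median values of 20.1 and 20.5 FPKM in the higher group.

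Among called genes with a defined ratio, the largest rise in the authors' deposited table was that of Sobic.005G184700 (chromosome 5, 66965526 to 66966456), which went from 0.0435 to 12.3 FPKM (log2 8.15, q = 0.0193). Second among called genes came Sobic.009G021400 (chromosome 9, 1908609 to 1909519), listed by the authors' deposited table at 0.0511 FPKM in ambient and 2.94 FPKM in elevated CO2 (log2 5.85, q = 0.0201). Both ambient values are close to 0, so the size of these ratios depends on very little expression: with a pseudocount of 1 FPKM the log2 changes were 3.67 and 1.91. The largest falls of called genes in the authors' deposited table were those of Sobic.009G014600 (chromosome 9, 1267111 to 1268591), from 6.27 to 0.396 FPKM (log2 -3.99, q = 0.00868), and of Sobic.003G370600 (chromosome 3, 68665572 to 68672699), from 3.81 to 0.241 FPKM (log2 -3.98, q = 0.00112). With a pseudocount of 1 FPKM these falls were -2.38 and -1.95 on the log2 scale. The files pair these identifiers with no gene name or function, and positions are those of the deposited loci. A large ratio did not suffice for a call: 272 of 1429 genes with a defined fall of at least 1 on the log2 scale, and 108 of 333 with such a rise, did not pass the authors' test.

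In 3 further called genes a group was listed at 0, so no ratio is given. A gene on chromosome 9 was listed at 0 in ambient and 7.67 FPKM in elevated CO2, and a gene on chromosome 5 at 0 and 3.05 FPKM. A gene on chromosome 10 was listed at 5.66 FPKM in ambient and 0 in elevated CO2. Among the 17849 genes without a test, 1146 were listed at 0 in elevated CO2 only, at no more than 2.23 FPKM in ambient. Another 1043 were listed at 0 in ambient only, at no more than 4.50 FPKM in elevated CO2.

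Called genes lay on all 10 chromosomes. Chromosome 5 had the highest share of called genes in both directions: 95 of its 778 tested genes fell (12.2%, against 8.88% elsewhere) and 29 rose (3.73%, against 2.35% elsewhere). Neither share passed Fisher's exact test after adjustment over the 20 tests by chromosome and direction (unadjusted p = 0.00252 and adjusted p = 0.0504 for falls, p = 0.0221 and adjusted p = 0.221 for rises). None of the other 18 shares passed either. The lowest share of falls was on chromosome 7 (84 of 1069 genes, 7.86%). On unplaced scaffolds 14 genes were tested, of which 1 rose.

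Genes that changed lay next to each other more often than shuffled calls did. Of 8667 pairs of neighbouring tested genes, both members fell in 178, against a mean of 70.8 and a maximum of 105 in 9999 shuffles within chromosomes (2.52 times, permutation p = 0.0001, the smallest these shuffles can give). Both members rose in 17 pairs, against a mean of 5.09 and a maximum of 16 (3.34 times, permutation p = 0.0001). Neighbours changed in opposite directions in 22 pairs, fewer than the shuffled mean of 38.0 (permutation p = 0.0033, one-sided). With calls at q under 0.01 there were 7 such pairs against a shuffled mean of 11.7, which did not pass (permutation p = 0.0952, one-sided).

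Some of these neighbours formed longer runs. There were 19 runs of at least 4 genes that fell, holding 82 genes, against a mean of 1.09 and a maximum of 5 such runs in 999 shuffles (permutation p = 0.001, the smallest these shuffles can give). The longest held 6 genes each. On chromosome 1, from 68610740 to 68684425, all 6 annotated genes fell by 1.88- to 3.58-fold, from between 57.9 and 166 FPKM in ambient CO2 to between 23.3 and 87.9 FPKM. On chromosome 4, from 46462820 to 46623262, 6 of 7 annotated genes fell by 2.36- to 5.68-fold, and the seventh was not tested. A run on chromosome 2, from 13354933 to 13393034, held 5 genes out of 6 that fell by 1.86- to 6.16-fold. Another on chromosome 1, from 19378850 to 19445592, held 5 adjacent genes that fell by 2.93- to 4.76-fold, the highest of them from 153 to 36.1 FPKM. All 4 genes between 3571339 and 3600689 on chromosome 9 fell by 2.91- to 5.64-fold. The runs of at least 4 genes that fell lay on chromosomes 1, 2, 3, 4, 5, 6, 9 and 10, and shorter runs are not listed by chromosome.

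Rises also formed runs, though short ones. There were 4 runs of 3 genes that rose, against a mean of 0.232 and a maximum of 3 in 999 shuffles (permutation p = 0.001). They lay on chromosome 1 (64901748 to 64938220, rises of 2.09- to 4.10-fold), chromosome 3 (71173868 to 71198882, 1.67- to 2.14-fold) and chromosome 6 (54733918 to 54759119, 1.997- to 2.57-fold, and 57422956 to 57438196, 2.10- to 2.68-fold). In the run on chromosome 3 the elevated values reached 230 FPKM, the highest among these runs. Whether the members of a run are copies of each other cannot be read from the table, and reads shared between such copies would make their values dependent.

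**Figure D2:**
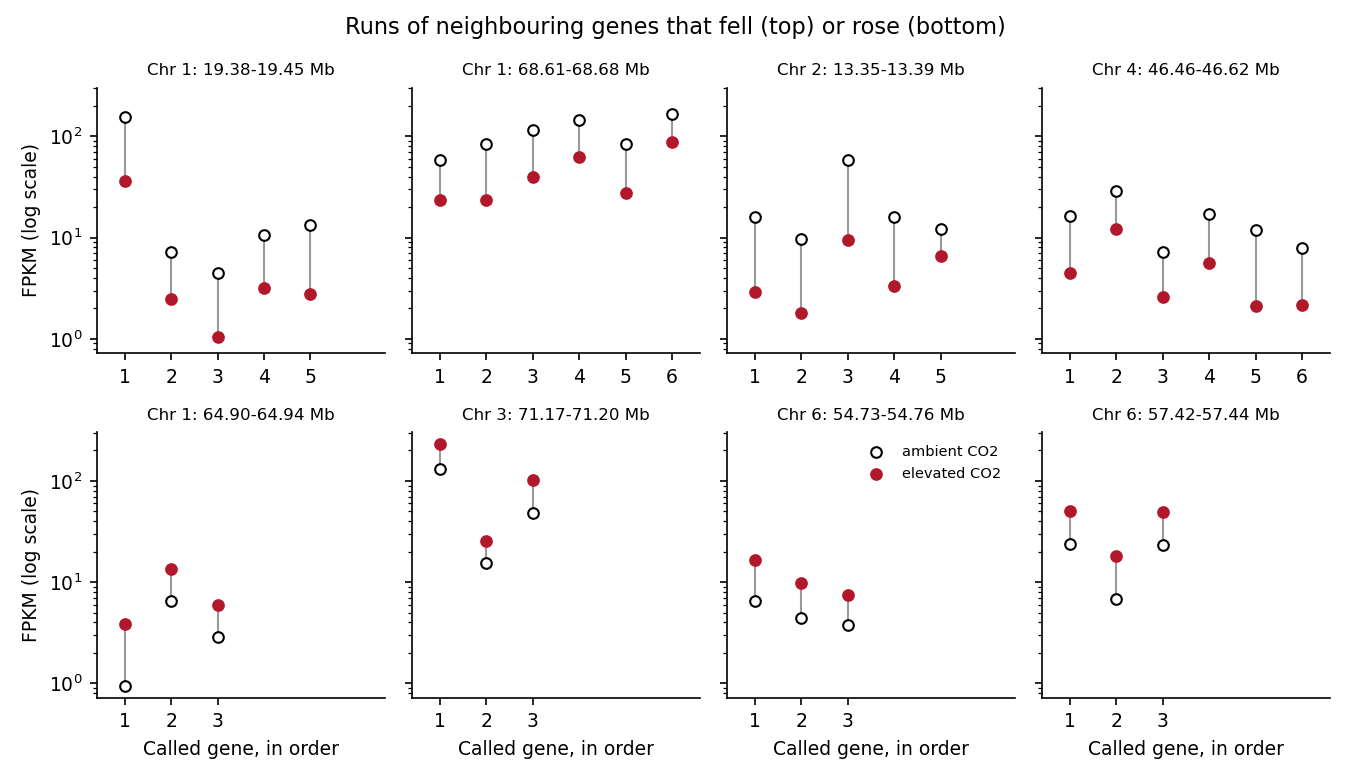
FPKM of the called genes in 8 runs, on a log axis, with open circles for ambient and filled circles for elevated CO2, in order along the chromosome; the upper row shows the 4 runs with at least 5 genes that fell and the lower row the 4 runs of genes that rose. In the longer run on chromosome 1 all 6 genes are above 23 FPKM in both groups, and the genes of a run differ in level while moving the same way.

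The share of genes called decreased with the span of the locus, in both directions. In the decile with the shortest loci (median 1017 bp) 248 of 1628 tested genes fell (15.2%, 95% Wilson interval 13.6 to 17.1%) and 78 rose (4.79%, 3.86 to 5.94%). Among the longest loci (median 12611 bp) 80 of 1628 fell (4.91%, 3.97 to 6.07%) and 10 rose (0.614%, 0.334 to 1.13%). For both directions together the difference was 14.5 percentage points, against a maximum of 5.28 in 9999 shuffles within expression deciles (permutation p = 0.0001, one-sided, the smallest these shuffles can give). Fold changes were also wider among short loci: the median absolute log2 fold change of tested genes was 0.50 in the shortest decile and 0.18 in the longest. Genes that share a deposited locus with an overlapping gene were called less often than the others. The shares were 102 of 1890 tested (5.40%) against 12.3% (Fisher's exact test, p = 1.54e-21). Such loci span all their genes, and the comparison was not matched on span or level. Genes of a common locus also come in groups, which this test does not take into account.

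**Figure D3:**
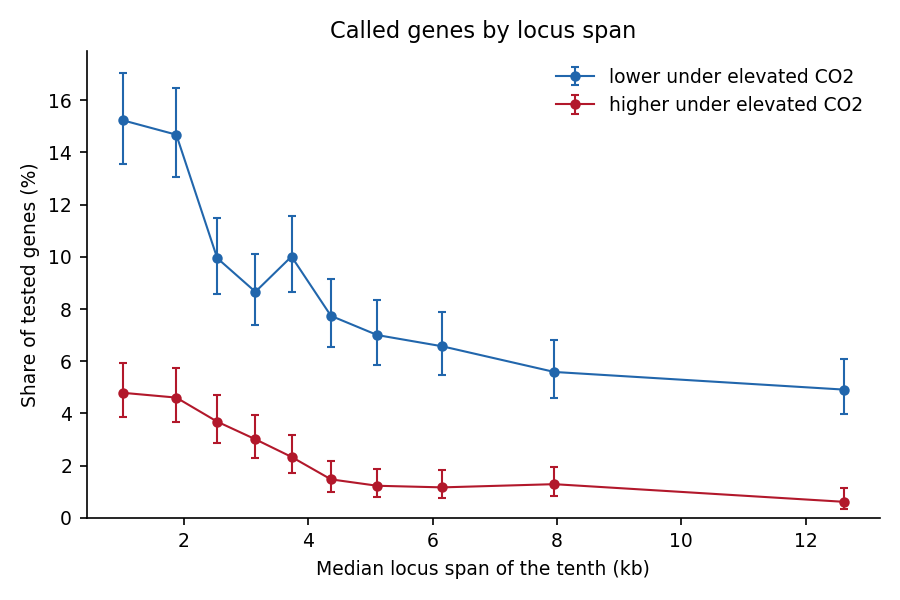
Share of tested genes that fell (blue) or rose (red), in percent, in each decile of locus span, placed at the decile's median span in kb; bars are 95% Wilson intervals, which cover counting error over genes only. The share that fell runs from 15.2% in the shortest decile to 4.91% in the longest, and the share that rose from 4.79% to 0.614%.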

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

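Genes that fell outnumbered genes that rose under every alternative run. With a deposited q under 0.01, 1159 genes were called, 974 lower and 185 higher (84.0% lower). Requiring an absolute log2 change of at least 1 left 227 higher genes and 83.6% lower, and with a pseudocount of 0.1 FPKM 223 higher and 83.8% lower. With a pseudocount of 1 FPKM and the same minimum, 1169 genes remained past both limits, 175 of them higher, and 85.0% lower. These counts differ because the limits admit fewer genes. Counting each run of neighbouring calls once, with a lone call as its own run, merges genes rather than dropping them. It gave 1564 runs, 1194 lower and 370 higher (76.3% of runs lower). Counts stayed within 1.5 times the reported ones when genes under 5 FPKM, genes with a common locus or genes with intermediate identifier numbers were left out; the last 2 and the runs were chosen after seeing the data. A minimum of 1 FPKM, a q recomputed over tested genes or over those of at least 1 FPKM, and centring on the median removed no tested gene or changed the sign of no called gene, so they test nothing about these counts. The rises of Sobic.005G184700 and Sobic.009G021400 did not pass q under 0.01, and the 2 named falls did. The excess of neighbouring pairs and the span difference kept their direction and stayed past p of 0.05 in all alternatives run for them. For pairs that both rose this rests on few pairs. At q under 0.01 there were 4 against a shuffled mean of 1.11 (permutation p = 0.0254). Without common loci and at least 10 kb apart there were 4 against 1.12 (permutation p = 0.0203). The deficit of neighbours that changed in opposite directions did not pass at q under 0.01 (0.598 times the shuffled mean, permutation p = 0.0952), where fewer genes are called, and passed in the other 3 alternatives. No paired analysis was possible because the table gives 1 pooled value per group, although the titles number the libraries 1 to 4 in both groups; for the same reason no library could be left out, no other split of the libraries could be tried, and no normalization between libraries was tried. The alternatives planned for the gene lists were not run, since no product names were at hand. Read depth is unknown, so what it limits could not be assessed beyond the 17849 genes that the authors did not test.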

Other observations

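Calls were compared between gene-poor and gene-rich regions. In the quintile of tested genes from the sparsest regions (up to 68 annotated genes per Mb) 271 of 3254 genes fell and 75 rose. In the densest quintile (134 to 164 genes per Mb) 277 of 3253 fell and 76 rose (Fisher's exact test, two-sided, adjusted p = 0.935 for both, over 2 tests). The 3 quintiles between them, in which 9.81%, 9.47% and 9.10% of tested genes fell, were not tested. Of the tests below, those of the overall median, of the trend with expression, of single libraries, of shared reads and of fragment length were chosen after the result was seen; the patterns themselves were all found in these data.

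The first pattern is the share of falls among called genes, 78.9%. A scaling difference between the groups would move all genes alike. The median log2 fold change of all tested genes was -0.028, and the median called fall was -1.35. Summed FPKM was 652743 in the ambient and 579715 in the elevated group. The authors' normalization is not given and may itself have set the median near 0, so these values cannot decide whether scaling contributed. A scaling bias that grows with expression level was also considered, since the medians of the expression deciles range from 0.05 to -0.15. In the 3 deciles with a median above 0 on the deposited scale, falls still made up 79.0% of the called genes (399 of 505, 95% Wilson interval 75.2 to 82.3%). On that scale this argues against the trend as the whole cause. A contribution of 1 library that stands apart cannot be told apart from a group effect, because 0 columns hold values per library; a change in the mix of cell types or a response to CO2 stays open and untested.

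Clustering of calls among neighbours is the second pattern. Overlapping loci are an unlikely sole cause: with common loci left out and pairs at least 10 kb apart, 51 of 1356 pairs both fell, 2.38 times the mean of shuffles among the same genes (permutation p = 0.0001). Shuffling within expression deciles and short or long span left a ratio of 2.47, which argues against like expression level and span class of neighbours as the whole cause. Span was held only as short or long, so likeness of span within these classes was not covered. For pairs that both fell the excess reaches beyond adjacent genes, at 2.10 times with 1 gene between, 1.38 times at a distance of 3 genes (permutation p = 0.002) and 1.48 times at 5 (permutation p = 0.001); it did not pass at 10 (1.14 times, permutation p = 0.131) or 20 (1.05 times, permutation p = 0.345). For pairs that both rose no excess passed with 1 gene between (1.60 times, permutation p = 0.133) or at distances of 3, 5 and 10 genes (permutation p = 0.231, 0.504 and 0.099); at 20 it was 2.13 times (permutation p = 0.027, not adjusted over the distances). Whether clustered neighbours are copies is unknown, because no sequence was at hand. Reads shared between neighbouring copies therefore cannot be told apart from shared regulation of neighbours, whether copies or not. Both stay open.

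The third pattern is the higher call rate of short loci. Loci shared by overlapping genes do not produce it, as the difference between the shortest and longest decile was 13.1 percentage points without them. Counting noise of short genes would fade with expression. At 20 FPKM or more in the higher group the difference was 25.1 points (30.5% against 5.42% called, permutation p = 0.0001). Called shares rise with level among tested genes in general, so a wider difference there cannot decide about counting noise. Read depth is unknown, so how small counting noise is at that level cannot be said, and a contribution of it stays open. A fragment length or RNA quality difference that only moved short genes one way would not alone raise the call rate in both directions. In the shortest decile 4.79% rose against 0.614% of the longest, and falls were more frequent too. Differences in fragment length or RNA quality among libraries could not be assessed, since no values per library were at hand. Locus span is also not transcript length, so this explanation stays open. Candidate explanations are that the gene classes responding to CO2 have compact loci, or that the authors' test has more power there. Neither was tested. The median absolute log2 fold change of all tested genes was 0.50 in the shortest decile and 0.18 in the longest. Power affects calls and not ratios, but counting noise, left open above, can widen the ratios of short genes. These values therefore cannot decide whether power is the whole cause.

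Some of the widest defined ratios were not called. Of 5 tested genes with a defined log2 rise of at least 5, the authors' deposited table called 2, and the smallest q of the other 3 was 0.536. The largest fall of tested genes with a defined ratio, 5.19 on the log2 scale, had q = 0.171 in the authors' deposited table. These counts leave out the 3 called genes listed at 0 in a group, 2 that rose and 1 that fell. Among genes without a test, 3 had at least 5 FPKM, the highest of them 47.9 FPKM in ambient CO2.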
